A study of Mus musculus with 8 samples.

How the data were processed

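Gene expression was measured on 8 Illumina mouse beadchip arrays, 1 colour, from spleen cells (splenocytes) of C57BL/6 mice of 3 p53 genotypes: wild type (WT), p53-null, and Δ122p53, which makes a p53 protein that lacks the N-terminal part. Per the labels, spleens of 4 mice aged 5 to 6 weeks were pooled. Treated cells received amsacrine, a topoisomerase II poison, at 1 µg per mL for 5 hours in a 30% ethanol carrier, or 4 Gy of gamma irradiation; the time between irradiation and harvest is not given in the sources used here. The labels gave 7 groups, with 2 p53-null control arrays and 1 array in each other group. Whether the controls received the carrier is not given in the sources used here. If they did not, effects of amsacrine and of its carrier cannot be told apart in the amsacrine responses. Whether the p53-null control pair came from separate pools or cultures is not given either, so p-values measure only the spread between these arrays, which may be technical.

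The authors deposited a table of probe signal intensities and detection p-values for 24613 probes. Per the file headers the table is non-normalized, and all intensities lay above 0 with no sign of background subtraction; the scanner software and the origin of the detection p-values are not given in the sources used here. The authors also deposited a table of normalized values, treated here as log2 values. Per the submitters' processing notes it was made with lumi, with no version or settings given. Its columns were quantile normalized: sorted values differed by at most 0.00052 between arrays, each column had a median of 7.3, and the values kept the rank order of the intensities on each array (Spearman 1). Pearson correlations with the values computed here were 0.972 to 0.973. Whether that table was variance-stabilised or log-transformed is not stated, so it served only as an alternative.

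In R 4.3.3 with limma 3.58.1, the intensities were corrected with neqc (background estimated from the detection p-values, offset 16), quantile normalized and put on the log2 scale. Median signal per array ran from 69.75 to 81.5, and 7710 to 8633 probes per array (31.3% to 35.1%) had a detection p under 0.01. With 1 or 2 arrays per group, the number of arrays limits the precision. Of the probes, 20984 had 1 gene symbol in the table that names them, 1 had several and 3628 were unnamed here. Symbols were updated through Entrez identifiers, of which 20968 matched the reference gene table. Probes detected on at least 1 array numbered 10273, of which 1363 had no single symbol and were left out. For each gene the probe with the highest mean was used, which gave 7456 genes. Trp53 had no probe in that table, so the level of the targeted gene, which would check the genotype labels, was not analysed here. Probe positions in the genome were not used here.

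Treatment responses were tested with limma in a model with a mean for each of the 7 groups. Its single residual degree of freedom came from the p53-null control pair, and a lone array was assumed to vary like that pair (prior degrees of freedom 4.78, prior SD 0.291). Genotype differences, and the amsacrine effect shared by the genotypes, came from an additive limma model of genotype and amsacrine on the 7 arrays without irradiation (3 residual degrees of freedom, prior 3.85, prior SD 0.292). Those degrees of freedom hold differences in response between genotypes as well as the spread of the control pair. Tests were 2-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. Counts at an unadjusted p under 0.05 include those due to chance, which alone would give a share of 0.05 of the 7456 genes. Differences are log2 values ± the standard error (SE) of the limma model. A gene not detected on any array of 1 side has only a bound, written as at least N-fold: the bright side's mean against, per array, the higher of the lowest signal among detected probes and the gene's own value. Other differences of the additive model can include arrays on which the gene was not detected, and their size is then not exact.

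The design, the gene lists and the rule for naming genes were set before the data were examined. The rule took the 8 largest differences each way in each treatment response and the 5 largest in each other comparison. Genes past the threshold came first. It added the 4 largest of each list, and always Cdkn1a and Mdm2. Of 26 lists of pathways and cell types, 24 had enough measured members for a median. The p53 family list had 0 measured members, and the sex-linked list had 2, Eif2s3y and Kdm5d. Each median was placed among 10000 random lists of the same size matched on expression in 20 bins; below the 2.5th or above the 97.5th percentile it is said to stand apart. This describes the arrays and is not a test. Lists were also tested with limma's camera in the additive model, with a preset correlation of 0.01 and with the estimated one. Tested on simulated data with 200 of 7456 genes shifted, the 7-group model recovered 8.9% of genes shifted by 2 (log2) and 87.6% of those shifted by 3 in the WT response. For the additive amsacrine effect the shares were 94.3% and 99.1%. Of genes shifted by 1, 0% were recovered in either. At a shift of 2, the unshifted genes called averaged 7.4 per run for the WT response and 9.9 for the additive effect. The simulated genotypes did not differ in their response, so the additive shares may be too high for these arrays. Alternatives covered background correction, scaling, filters, all probes, an intensity trend, the authors' value table and leaving out arrays.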

Results

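Expression of 7456 genes was compared across 8 arrays of mouse splenocytes. The groups were WT control, WT amsacrine, p53-null amsacrine, p53-null irradiated, Δ122p53 control and Δ122p53 amsacrine, with 1 array each, and p53-null control with 2 arrays. The p53-null control pair gave the spread for the treatment responses. Between those arrays 495 genes (6.6%) differed at least 2-fold, and the median absolute difference was 0.30 (log2). Among the lists, neutrophil and immediate early genes differed most within this pair. Immediate early genes, transcribed within minutes of a stimulus, had a median 1.38 higher on control 2, and all 13 neutrophil genes were higher there (median 1.56). In all, 13 of the 24 list medians stood apart between these controls. The plot of list medians shows the pair beside the treatment responses, while the text compares only some lists with it. Control 2 minus control 1 gave medians that stood apart for NK cell (0.58), stress response (0.32) and ribosome biogenesis genes (0.29). The same held for mitotic (0.27), DNA replication (0.24) and interferon response genes (-0.23). Macrophage (-0.13), B cell (-0.17), T cell (0.11) and p53 target medians (-0.09) did not stand apart. Over all genes, the arrays most unlike each other were Δ122p53 amsacrine and WT control (r = 0.812 across genes), against r = 0.962 for the control pair. Null control 2 was nearer to the WT control (r = 0.976) than to null control 1, which was at 0.936 with the WT control.

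The WT response addressed what amsacrine, given in its ethanol carrier, does to splenocytes with intact p53. Targets of p53 were higher after the drug, while B cell, macrophage and cell division genes were lower. Phlda3, a p53-induced inhibitor of Akt signalling, was at least 11.9-fold higher. Mdm2, which encodes the ligase that degrades p53, was higher by 2.21 ± 0.38, and Slc19a2 by 3.27 ± 0.40. Polk, a translesion DNA polymerase, was at least 7.36-fold higher. Cdkn1a, the p21 cell cycle inhibitor, was higher by 3.07 ± 1.30, with a wide error because the null control arrays differed by 2.99 for this gene. Of the 31 measured p53 targets, 23 were higher, 16 at least 2-fold, and their median was 1.13 (100th percentile; 0.72 with undetected genes at their bounds). The DNA damage sensor gene Ddb2 was higher by 1.46 ± 0.38, although 1 of its 3 other probes had the opposite sign. Among genes outside the lists, the G protein subunit gene Gng4 was at least 16.3-fold, the glycoprotein gene Gpnmb at least 11.5-fold and Cables1 at least 7.03-fold higher, and the lipid enzyme gene Dgat1 was higher by 3.43 ± 0.38. Bcl2l11, which encodes the pro-apoptotic protein Bim, was at least 5.53-fold higher, although the apoptosis list had a median of -0.06.

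B cell, macrophage and cell division genes were lower in treated WT cells. Among 12 B cell genes the median was -1.38, with Cd22 at least 5.5-fold lower and Cd79a, part of the antigen receptor, at -2.64 ± 0.38. Among 12 monocyte and macrophage genes the median was -1.86, with the mannose receptor gene Mrc1 at least 5.47-fold lower and the complement gene C1qb at -2.20 ± 0.38. The mitotic median was -1.27 (-0.87 with undetected genes at their bounds), led by Birc5 (survivin) at -2.51 ± 0.39, and that of DNA replication genes was -0.60 (-0.30 with bounds), with Uhrf1 at -2.24 ± 0.46. Immediate early genes had a median of -0.70, including Fosb, at least 17.3-fold lower, and Fos at -3.06 ± 0.78. This list differed by more than that median between the untreated null controls. Ribosome biogenesis genes were higher (median 0.78). No gene passed the threshold in limma over all genes: 0 at adjusted p under 0.05, with a smallest value of 0.0666, and 1471 at an unadjusted p under 0.05. Adjusted over the list alone, 13 p53 targets were higher and 1 lower, 8 B cell, 10 macrophage and 7 mitotic genes were lower, against 0 over all genes. At least 2-fold differences were seen for 1625 genes, 723 higher and 902 lower, but for 910 with a normexp background at offset 50 and 521 in the authors' value table.

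**Figure D1:**
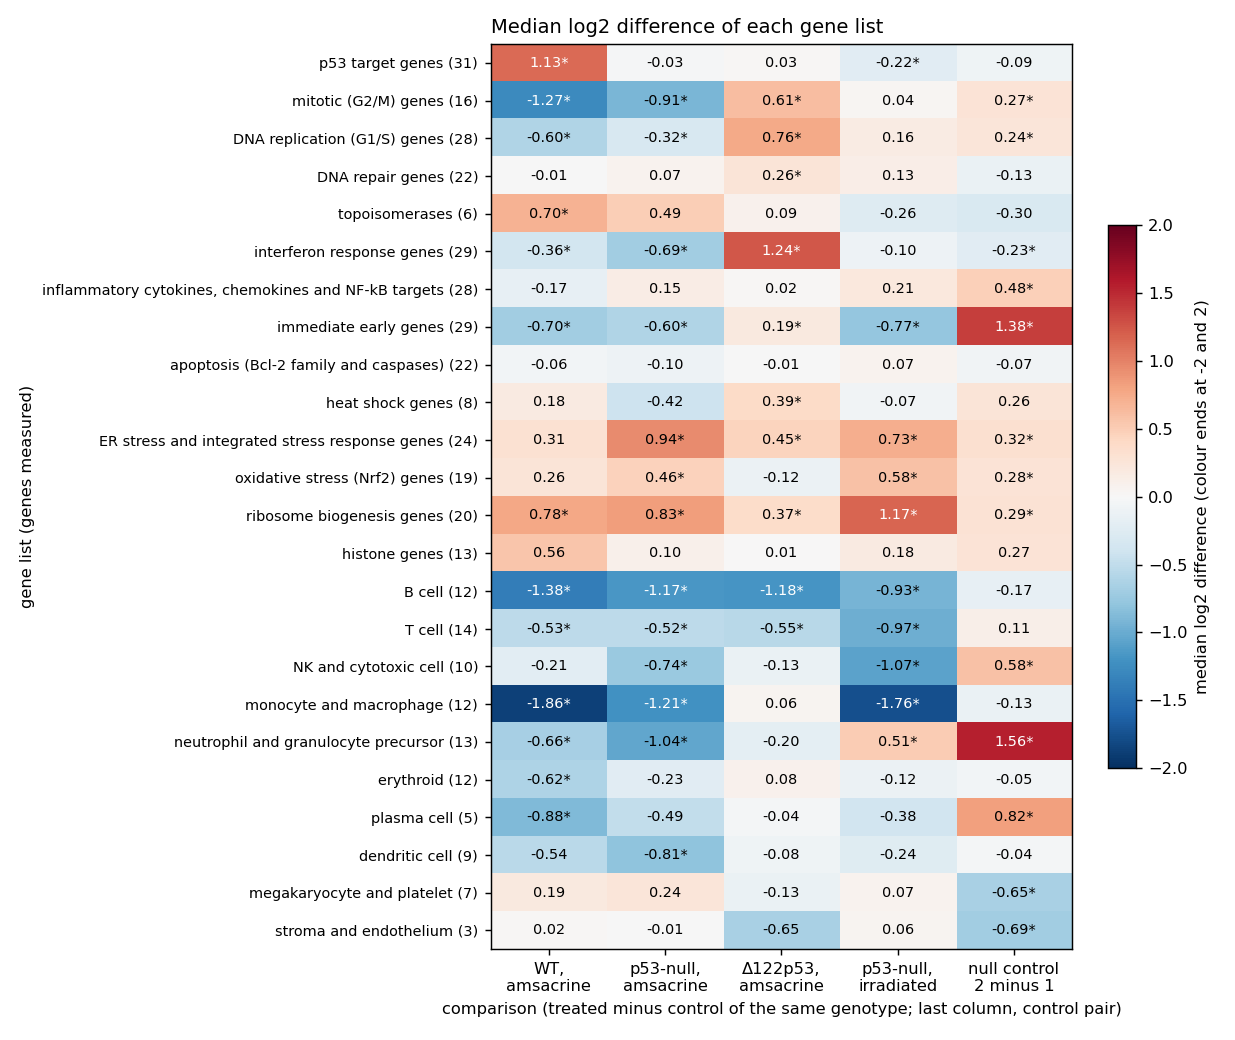
Median log2 difference of 24 gene lists (number of measured genes in brackets) in the 4 treatment responses and between the p53-null controls; red is higher, blue lower, and an asterisk marks a median that stands apart from random lists. The p53 target median was 1.13 in WT and -0.03 in p53-null cells after amsacrine, and the interferon median was 1.24 in Δ122p53 cells.

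In p53-null cells the same dose of amsacrine was compared with 2 controls, to see which changes need no p53. The genes that rose were Gpnmb, at least 22.4-fold (adjusted p = 0.0285), Gng4, at least 13.3-fold, the neutral amino acid transporter gene Slc1a4, at least 7.51-fold, Cables1, at least 8.31-fold, and Trib3, a pseudokinase gene induced by Atf4, at least 10.6-fold. The genes that fell were the kinase gene Srpk3 (-4.39 ± 0.33), haptoglobin gene Hp, at least 15.4-fold, the B cell receptor inhibitor gene Cd22, at least 11.2-fold, Fgd2 (-3.80 ± 0.35) and Ffar2, at least 5.06-fold. Trib3 belongs to the genes of endoplasmic reticulum stress and the integrated stress response, of which 12 of 24 were at least 2-fold higher. Their median was 0.94 (0.75 with bounds), and other members were the glutathione-degrading enzyme gene Chac1 at 3.58 ± 0.48 and the folate enzyme genes Mthfd2 at 2.29 ± 0.33 and Shmt2 at 2.27 ± 0.32. In this list 1 gene passed over all genes, and adjusted over the list alone 11 were higher and 2 lower.

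The p53 targets had a median of -0.03 in these cells, with Mdm2 at 0.36 ± 0.33, Ephx1 at -1.53 ± 0.32 and Cdkn1a, detected on 1 of the 2 controls, at 1.76 ± 1.13. The B cell median was -1.17, with 1 gene (Cd22) past the threshold over all genes and 6 lower adjusted over the list alone. For macrophage genes the median was -1.21, for neutrophil genes -1.04, for NK cell genes -0.74 and for mitotic genes -0.91 (-0.55 with bounds). The neutrophil list differed by more than its median here between the null controls alone. Interferon response genes were lower in 27 of 29 cases (median -0.69; -0.44 with bounds), with Oas2 at least 2.45-fold lower. The oxidative stress gene Srxn1 was at least 4.12-fold higher, and Bcl2l11 was higher by 3.04 ± 0.43. The limma test called 10 genes and 1285 had an unadjusted p under 0.05; 1080 differed at least 2-fold. The 10 calls were sensitive to processing: 0 genes passed with either other background setting, with cyclic loess, in the authors' value table or with no detection filter, and 32 passed among genes detected on all arrays.

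In Δ122p53 cells, interferon-induced and cell cycle genes were higher after amsacrine. The chemokine gene Cxcl10 was at least 14.3-fold higher and Cxcl9 higher by 2.54 ± 0.41. The antiviral gene Ifitm3 was higher by 1.90 ± 0.39, and Irf7, a transcription factor of the interferon response, by 1.89 ± 0.40. All 29 measured interferon genes were higher, 19 at least 2-fold (median 1.24). Of the DNA replication genes, 27 of 28 were higher (median 0.76), led by Mcm10 at 2.14 ± 0.38, and of the mitotic genes 14 of 16 (median 0.61), with Aurkb at 1.26 ± 0.39. The p53 targets had a median of 0.03, with Mdm2 at 0.05 ± 0.38, Cdkn1a at 0.60 ± 1.30, the death receptor gene Fas at 1.25 ± 0.38 and Ephx1 at -2.61 ± 0.37. B cell genes were lower here too (median -1.18), with Cd22 at least 7.24-fold lower and Blk at -2.16 ± 0.38. Ciita, the regulator of MHC class II genes, was at -2.55 ± 0.58 and H2-DMb1 at -2.58 ± 0.40. The macrophage median was 0.06 (0 with bounds), but 4 of the 12 genes were undetected on both arrays and 2 on 1 of them. On the Δ122p53 control the median level of this list was 6.67, against 9.53 on the WT control. The lowest detected signal on the Δ122p53 control was 5.96, which leaves little room for a fall. In limma 0 genes passed, with a smallest adjusted p of 0.385 and 514 genes at an unadjusted p under 0.05; adjusted over the list alone, 14 interferon genes and 1 replication gene were higher, against 0 over all genes. The number of genes that differed at least 2-fold, 545, was near the 495 between the control arrays, and was 155 in the authors' value table.

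The responses were then set against each other. Across genes, the WT and p53-null responses correlated at r = 0.78 (Spearman rho 0.76), against 0.16 (0.14) for WT and Δ122p53 and 0.24 (0.22) for p53-null and Δ122p53; genes are not independent replicates. For WT minus null, the lipid enzyme gene Scd2 differed between the responses by 3.62 ± 0.50 and Mdm2 by 1.85 ± 0.50. Phlda3, Polk and Trim7 were also among the largest differences of responses, but were not detected in some of the groups and have no exact difference. On the amsacrine arrays p53-null cells had at least 10.8-fold less Phlda3, 6.68-fold less Polk and 2.11-fold less Trim7 than WT cells. For the p53 targets the difference had a median of 1.00, with 27 of 31 higher in WT. Adjusted over the list alone 9 targets passed in limma, but 0 did over all genes (smallest adjusted p 0.644). At an unadjusted p under 0.05 there were 113 genes, fewer than chance alone would give. For Δ122p53 minus WT the p53 target median was -1.13, with 10 lower adjusted over the list alone. Phlda3 was not detected in Δ122p53 cells and was at least 12.1-fold lower there than in WT cells after amsacrine. Ppp1r16b, which encodes a phosphatase subunit, was at -2.49 ± 0.39 in the Δ122p53 response and rose at least 6.03-fold in WT, while the interferon median was 1.64 (8 higher adjusted over the list alone). For Δ122p53 minus p53-null the interferon median was 1.71, with 17 higher adjusted over the list alone. Cxcl9 fell at least 2.66-fold in p53-null cells against its rise in Δ122p53 cells, and Gpnmb stood at 0.06 ± 0.38 in the Δ122p53 response against a rise of at least 22.4-fold in p53-null cells. These medians include genes not detected in some of the groups. Over all genes the limma test of these differences called 0 genes, with 804 and 622 at an unadjusted p under 0.05, so no single gene is shown to respond differently between genotypes.

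**Figure D2:**
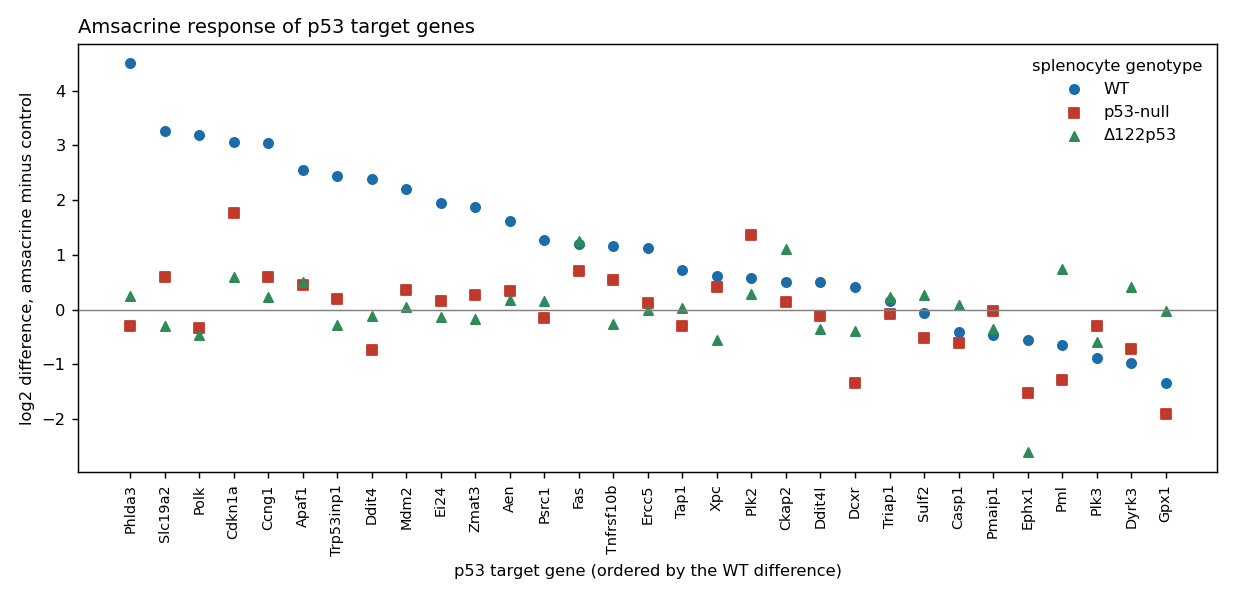
Log2 difference, amsacrine minus control, of 31 p53 target genes (horizontal axis) in WT (circles), p53-null (squares) and Δ122p53 (triangles) splenocytes. The list median was 1.13 in WT, -0.03 in p53-null and 0.03 in Δ122p53 cells; SEs are omitted, and Cdkn1a had the SE of 1.30 given in the text.

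The amsacrine effect common to the 3 genotypes came from the additive model. Genes of B lymphocytes fell: Cd22 by at least 7.63-fold (adjusted p = 0.0023, lower in all 3 genotypes), Bank1 (-2.44 ± 0.31), Cd79a (-1.96 ± 0.26) and Fcmr (-1.80 ± 0.21). The lymphoid transcription factor gene Bcl11a (-2.73 ± 0.24), Srpk3 (-3.97 ± 0.31) and the T cell genes Lat (-1.96 ± 0.19) and Bcl11b (-1.46 ± 0.21) also fell. Gng4 rose at least 10.5-fold (adjusted p = 0.012), with Slc1a4 (2.89 ± 0.52), Dgat1 (2.37 ± 0.38) and the transporter gene Slc43a3 (2.00 ± 0.27). Slc1a4 was not detected on the WT or p53-null controls. Srpk3, Bank1 and Lat were not detected on the Δ122p53 amsacrine array, so the sizes for these genes and for Slc1a4 are not exact. The replication gene Pold1 fell (-0.98 ± 0.18) and the histone gene H4c8 rose (1.07 ± 0.17). In the B cell list 5 of 12 fell over all genes and 11 adjusted over the list alone, with a camera adjusted p of 3.16e-09 and an adjusted p = 0.157 with an estimated correlation. In the T cell list 2 of 14 fell, 7 adjusted over the list alone, with 0.000312 in camera and adjusted p = 0.277 with an estimated correlation. Ribosome biogenesis genes had a median of 0.71 (6.98e-06 in camera, adjusted p = 0.714 with an estimated correlation). Cdkn1a (1.81 ± 0.74) and Mdm2 (0.82 ± 0.39) did not pass. In all 157 genes passed, 30 higher and 127 lower, but 1 passed without null control 1 and 1 without null control 2. Without the Δ122p53 arrays, a choice made after seeing the data, 1265 passed.

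In p53-null cells gamma irradiation was compared with the same controls and with amsacrine. Stress response and ribosome biogenesis genes were higher: Trib3 at least 6.06-fold, Shmt2 by 2.67 ± 0.32 and the nucleolar gene Nolc1 by 1.71 ± 0.35. Slc1a4, which is on neither list, was at least 4.33-fold higher. All 20 ribosome biogenesis genes were higher (median 1.17), 17 of them adjusted over the list alone, and the stress response list had a median of 0.73, with 10 higher adjusted over the list alone. Gpnmb was at least 8.88-fold and the oxidative stress gene Srxn1 at least 3.6-fold higher. Macrophage genes were lower (median -1.76, 7 adjusted over the list alone), with Mrc1 at least 4.82-fold lower and C1qa at -2.10 ± 0.35. NK cell genes had a median of -1.07, led by Nkg7 at -2.66 ± 0.33, T cell genes -0.97, with Thy1 at -1.40 ± 0.32, and B cell genes -0.93, with Cd22 at -2.66 ± 0.34. Immediate early genes had a median of -0.77, with Fosb at least 10.8-fold lower, but this list differed by more than that between the null controls alone. The mitotic median was 0.04, and that of irradiation minus amsacrine was 1.06 (0.40 with undetected genes at their bounds). The p53 target median was -0.22 (-0.10 with bounds), with Cdkn1a at 2.40 ± 1.13 and Mdm2 at -0.59 ± 0.33. Neutrophil genes had a median of 0.51, but -0.21 without null control 1. In limma 0 genes passed for irradiation against control (smallest adjusted p 0.13; 1036 at an unadjusted p under 0.05) and 0 for irradiation against amsacrine (791). At least 2-fold differences numbered 816, and 1261 without null control 2. Across genes the irradiation and amsacrine responses correlated at r = 0.53 (rho 0.42). They share their controls, which alone gave r = 0.33 in simulation. The covariance was 0.25 against 0.048 simulated. With control 1 used for irradiation and control 2 for amsacrine r was 0.17 (rho 0.09), and 0.51 (0.45) the other way round, a split chosen after seeing the data, so the size of the correlation depended on the controls.

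The Δ122p53 arrays differed most from the other genotypes, in red cell, interferon and proliferation genes. Against WT over control and amsacrine arrays, the erythroid genes Trim10 and Hemgn rose at least 16.5-fold and 20.4-fold (adjusted p = 0.000463 for each), Rhag, part of the red cell Rh complex, at least 13.2-fold, and the Kell blood group gene Kel by 5.00 ± 0.42. Against p53-null, the red cell anion exchanger gene Slc4a1 rose by 6.09 ± 0.38, the water channel gene Aqp1 by 5.93 ± 0.69 and Tspan33 at least 28.0-fold. Kel was not detected on the WT amsacrine array, nor Aqp1 on the p53-null amsacrine array, so their sizes are not exact. In the erythroid list 9 of 12 rose against WT (median 4.02) and 10 against p53-null (4.78); adjusted over the list alone 11 were higher in each. Its camera adjusted p of 5.89e-13 and 9.74e-18 was lost: adjusted p = 0.238 and adjusted p = 0.153 with an estimated correlation. Interferon response genes rose in 22 of 29 cases against WT (median 3.0) and 18 against p53-null (2.31), 24 in each adjusted over the list alone. The medians were 1.85 and 1.25 on the control arrays (9 and 4 genes past the threshold) and 3.64 and 3.49 on the amsacrine arrays (24 and 22). Over both conditions Rsad2 was at 4.57 ± 0.35 and 4.55 ± 0.33. The estimated correlation was high in this list, with adjusted p = 0.482 and adjusted p = 0.419 with an estimated correlation. Mitotic genes rose in 13 of 16 cases against WT (median 2.55) and 12 against p53-null (2.29), with 14 and 16 adjusted over the list alone. On the control arrays the medians were 1.51 and 1.62 (1 and 5 genes past the threshold), and on the amsacrine arrays 3.43 and 3.34 (14 and 13). Cdk1, the mitotic kinase, was at 4.31 ± 0.53 against WT, and Top2a, a target of amsacrine, at 2.69 ± 0.41. Cdk1 was not detected on the WT amsacrine array, so its size is not exact. For the mitotic list camera gave adjusted p = 0.482 and adjusted p = 0.418 with an estimated correlation. In the stress response list Asns, asparagine synthetase, rose by 3.58 ± 0.43 against WT and by 4.01 ± 0.39 against p53-null.

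Macrophage and T cell genes fell in the same comparisons, and markers of other cell types were lower too. Against WT and p53-null, NK cell genes had medians of -1.42 and -0.97 and B cell genes -0.53 and -0.60. Megakaryocyte genes had -1.41 and -1.05 (-0.21 and -0.11 with bounds). Of 12 macrophage genes, 7 fell against WT (median -2.14) and 8 against p53-null (-2.12), among them the complement gene C1qc, at least 6.93-fold and 4.92-fold lower, and Vcam1 against WT (-3.07 ± 0.48). On the control arrays the medians were -3.14 and -2.84 (7 and 8 genes past the threshold), and on the amsacrine arrays -1.37 and -1.48 (0 and 0). With an estimated correlation the list gave adjusted p = 0.482 and adjusted p = 0.419 with an estimated correlation. Of 14 T cell genes 9 fell in each comparison (medians -1.40 and -1.28), including Lat (-2.77 ± 0.24 and -2.15 ± 0.22), and camera gave adjusted p = 0.238 and adjusted p = 0.153 with an estimated correlation. Psmb1, a proteasome subunit gene, fell by 3.92 and fell by 3.79; probe sequences were not used here, so a strain variant under its probe is not ruled out. Also lower was the pancreatic amylase gene Amy2a5, at least 16.7-fold and 8.04-fold. The p53 target median was -0.53 against WT, with 21 of 31 lower (0.48th percentile; -0.42 with bounds), and -0.08 against p53-null. Split by treatment, the p53 target median against WT was -0.13 on the control arrays (0 with bounds). On the amsacrine arrays it was -1.07 (-1.04 with bounds). Past the threshold 5 p53 targets rose and 4 fell against WT, and 4 rose and 0 fell against p53-null. Among them were Gpx1 at 2.53 ± 0.45 and Dcxr at least 4.37-fold lower against WT. Mdm2 (-1.11 ± 0.50 and -0.48 ± 0.47) and Cdkn1a (0.06 ± 0.96 and 2.39 ± 0.89) did not pass. Against WT 1067 genes passed, 496 higher and 571 lower, and 630 passed against p53-null, 358 higher and 272 lower. The median of all genes was -0.14 and -0.07. Against WT, cyclic loess gave 491 higher and 410 lower, and all probes 817 and 645. The other background and filter settings kept more lower than higher. A genotype's control and amsacrine arrays may come from 1 pool, so these tests may not measure the spread between mice. Higher in both comparisons were 303 genes and lower in both 222, against 23.8 and 20.8 for independent lists. The comparisons share the Δ122p53 arrays, so part of the overlap may come from those arrays. A simulation gave 0.01 and 0, but it held no changed gene and so cannot show how large that part is. The count against WT was 642 without null control 1, and that against p53-null was 233 without null control 1 and 300 without null control 2.

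**Figure D3:**
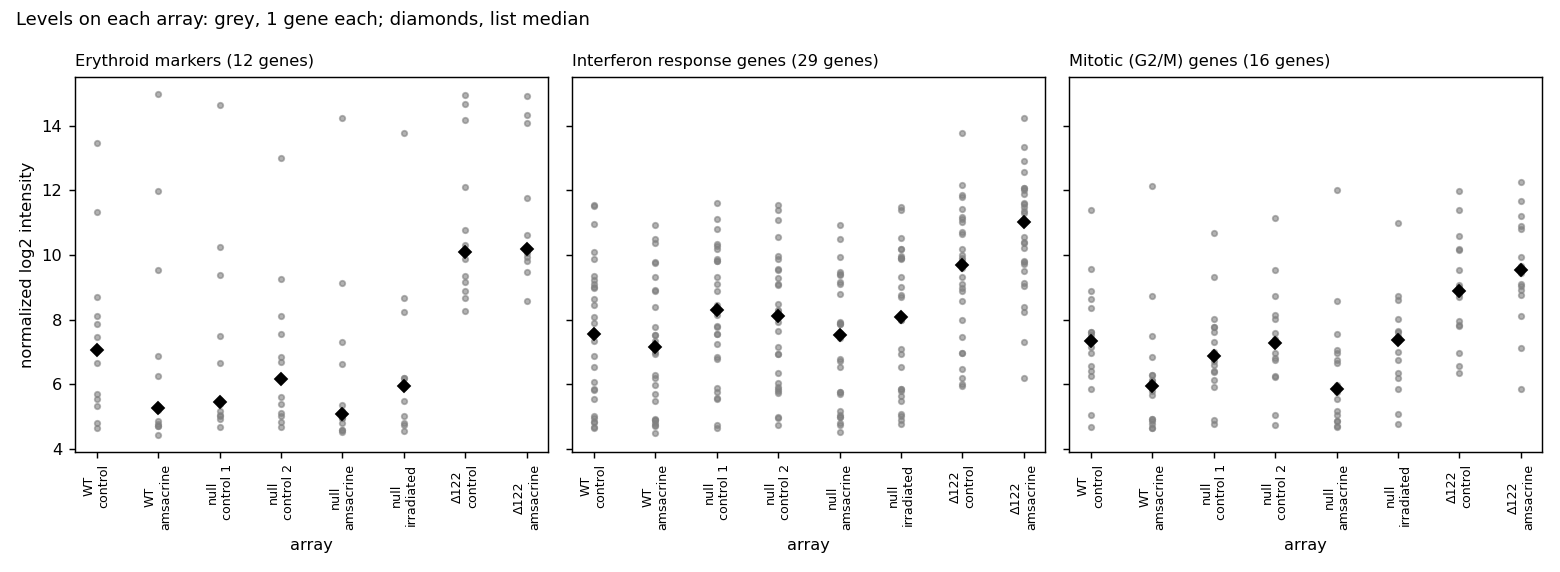
Normalized log2 intensity of erythroid (12), interferon response (29) and mitotic (16) genes on each of the 8 arrays; grey points are genes and diamonds list medians. The erythroid median was 10.09 and 10.19 on the Δ122p53 arrays and at most 7.06 on the others.

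The last comparison, p53-null against WT over control and amsacrine arrays, asked what loss of p53 alone changes. Among the genes lowest in p53-null cells were the p53 targets Cdkn1a (-2.33 ± 0.89), Phlda3, at least 2.38-fold lower, and Slc19a2 (-2.02 ± 0.70), with the repair gene Mgmt (-2.17 ± 0.35) and Slc4a1 (-2.02 ± 0.38), which are not on that list, and Mdm2 was at -0.63 ± 0.47. On the other side were the kinase gene Snrk, at least 1.86-fold higher, and the viral RNA sensor gene Ddx58, higher by 1.61 ± 0.53. The p53 target median was -0.47 and the interferon median 0.40 (0.17 with bounds). Split by treatment, the p53 target median was 0.02 between the control arrays and -1.02 between the amsacrine arrays. None passed in limma: 0 genes, with 772 at an unadjusted p under 0.05 and adjusted p of 0.472 for Cdkn1a.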

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

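The count of other splits of the arrays was planned; all other tests in this part were chosen only after the results were seen. No group held enough arrays for a check of single outlying arrays. What stood out were amsacrine responses that ran in opposite directions in Δ122p53 cells and in the other genotypes; the differences between list medians were not tested, and the tests of single genes called 0 over all genes. Adjusted over the list alone, 11 of 16 mitotic, 10 of 28 replication and 8 of 29 interferon genes passed for Δ122p53 minus WT, and 6, 0 and 17 for Δ122p53 minus p53-null. The median was 0.61 for mitotic genes in Δ122p53, against -1.27 in WT and -0.91 in p53-null cells. DNA replication genes stood at 0.76, against -0.60 and -0.32. Interferon response genes stood at 1.24, against -0.36 and -0.69. With undetected genes at their bounds the falls in WT and p53-null cells were smaller: -0.87 and -0.55 for mitotic, -0.30 and -0.14 for replication and -0.10 and -0.44 for interferon genes, against 0.61, 0.68 and 1.24 in Δ122p53. Immediate early genes stood at 0.19, against -0.70 and -0.60, and moved by 1.38 between the p53-null controls alone. The chemokine gene Cxcl9 was at 2.54 in Δ122p53, -1.56 in WT and -1.64 in p53-null cells; it was not detected after amsacrine in the last 2, so only falls of at least 2.8-fold and 2.66-fold are shown. The phosphatase subunit gene Ppp1r16b was at -2.49 in Δ122p53, against 3.38 and 2.36; it was not detected on the WT or p53-null controls, so only rises of at least 6.03-fold and 3.18-fold are shown.

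p53 target genes were higher after amsacrine in WT and not in p53-null cells. The choice of null control, scaling or filter is argued against: the WT-minus-null median of 1.00 stayed at 0.93 or more over those alternatives, and at 0.62 or more with normexp, with no background correction and in the authors' table. A low starting level on the WT control array stays open. The p53-null controls minus the WT control gave a target median of 0.02, with 16 of 31 higher, but cells without p53 do not show what level a WT control should have. The amsacrine arrays differed by -1.02 (p53-null minus WT). A p53-dependent response and a difference between pools stay open too, since the WT pair of arrays has no replicate.

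Erythroid and mitotic genes were higher on both Δ122p53 arrays. Scaling between arrays is argued against: for Δ122p53 control minus the null controls, the medians were 4.73 and 1.62 with scaling and 4.53 and 1.46 without it. With background correction dropped as well they were 3.39 and 0.98. A larger share of erythroid precursors, which divide, is a candidate explanation. Of 31 measured erythroid genes that were not on the fixed list, at least 30 were higher in each of the 4 comparisons of single conditions. These genes were chosen before this test was run, but after the rise of the fixed list had been seen. Any gene detected only on the Δ122p53 arrays counted as measured because it was high there, and the 4 comparisons share those arrays. This count therefore cannot decide the question. Genotype and pool of mice cannot be told apart, because each genotype's control and treated cells may come from 1 pool; the Δ122p53-minus-WT differences of the control and of the amsacrine arrays correlated at r = 0.57 across genes.

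The Δ122p53 control array lay part of the way along the amsacrine response of the other genotypes. Across genes, Δ122p53 control minus the null controls correlated with the WT response at r = 0.43 (0.33 and 0.49 with each null control alone), and of 85 genes at least 4-fold higher in the WT response 67 were higher on that control. Exchanged Δ122p53 labels stay open. Of 736 genes at least 2-fold apart the same way in the WT and p53-null responses, 66.3% moved that way in the Δ122p53 response, where an exchange would turn the sign, but 63.3% did so in null control 1 minus null control 2. Among the 476 of them less than 0.5 apart between the null controls the share in Δ122p53 was 68.1%. B cell medians were below 0 in all 3 responses (-1.38, -1.17 and -1.18), though of these genes only Cd22, in p53-null cells, passed over all genes. The mitotic, replication and interferon medians above ran in the direction that an exchange would give. Handling of the cultures could move the same genes: null control 1 minus null control 2, with no drug, correlated with the WT response at r = 0.33. Genotype and culture conditions cannot be told apart with 1 Δ122p53 control array.

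For the amsacrine effect over the 3 genotypes, 157 genes passed, and 2 of the 34 splits of the 7 arrays that could be fitted, the real one included, gave as many, so chance is not excluded by this count. The highest other split gave 1093 genes. It set the 3 WT and p53-null control arrays against the remaining 4, and so grouped the Δ122p53 control with the treated arrays, which points to the structure of the samples described above.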

How the results depend on the processing

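The settings with a subset of arrays (without the Δ122p53 arrays, control or amsacrine arrays only), the WT response against the mean of the other responses (0 genes, as for WT minus p53-null) and camera on the genotype differences were chosen after seeing the data; all others were planned. Across alternatives, 110 of 158 counts and correlations, 1534 of 1704 list medians and 7065 of 7549 values of named genes kept their direction and their side of the threshold or stayed within the limits set. Many of the 110 were counts of 0 that stayed 0, so that share says little about the other counts. All 31 of 96 camera calls made with the preset correlation were lost with the estimated one. Genes at least 2-fold apart, with 1625 (WT amsacrine), 1080 (p53-null amsacrine), 545 (Δ122p53 amsacrine), 816 (irradiation) and 495 (control pair), numbered 910, 578, 263, 414 and 207 with normexp at offset 50, 965, 611, 273, 439 and 224 with no background correction, and 521, 342, 155, 235 and 116 in the authors' value table. The control pair then split 157 higher and 50 lower with normexp, 166 and 58 with no correction and 90 and 26 in the authors' table (320 and 175 otherwise), and Δ122p53 amsacrine 55 and 100 in the authors' table (252 and 293 otherwise). Leaving out each null control gave 1064 to 1452 for p53-null amsacrine and 806 to 1261 for irradiation.

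The 10 calls for p53-null amsacrine became 0 with normexp, no background correction, cyclic loess, the authors' table and no detection filter (15967 genes tested), 32 among the 4878 genes detected on all arrays (9 higher, 23 lower) and 24 with an intensity trend (8 and 16), which also gave 2 for WT amsacrine. The 157 for the shared amsacrine effect became 103 with normexp, 42 in the authors' table, 94 with no filter, 1 to 1 without each null control and 1265 without the Δ122p53 arrays. Δ122p53 minus p53-null (630) gave 344 in the authors' table, 400 with no filter, 233 to 300 without each null control, 308 on control arrays only and 229 on amsacrine arrays only (211 higher, 18 lower). Δ122p53 minus WT (1067) gave 687, 656, 642 to 739, 233 and 305 (227 and 78). For p53-null minus WT every setting gave 0. The correlation of WT and p53-null responses (0.78) was 0.80 with normexp and with no correction, 0.81 in the authors' table, 0.75 with no filter and 0.65 to 0.81 without each null control; that of p53-null and Δ122p53 (0.24) was 0.19 to 0.26. The cause was not tested.

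With null control 1 or 2 left out, 7 list medians reversed in 1 of the 2 settings. Without control 1 and without control 2, immediate early genes gave 1.25 and -0.09 (Δ122p53 minus p53-null response), 0.40 and -0.99 (WT minus p53-null response) and -1.21 and 0 (p53-null amsacrine). Neutrophil genes gave 0.87 and -0.15 (WT minus p53-null) and -0.21 and 1.25 (irradiation), inflammatory genes 0.06 and -0.52 (WT minus p53-null) and megakaryocyte genes -1.34 and 0.21 (Δ122p53 minus p53-null). The cause was not tested. Arrays were not paired by pool of mice, because the labels do not tie arrays to pools. The additive model did compare amsacrine with control within each genotype. A chip as block was not run, since the files name no chips, and 7-group models without 1 null control had no residual degrees of freedom, so they gave values with no test. Signal over background limits the genes below detection, for which only bounds are given.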

Other observations

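The 3 hypotheses below, and their tests, were chosen only after the results were seen. Medians of other fixed lists follow. In the order WT, p53-null and Δ122p53 amsacrine and p53-null irradiation, DNA repair genes had medians of -0.01, 0.07, 0.26 and 0.13, apoptosis genes -0.06, -0.10, -0.01 and 0.07, inflammatory genes -0.17, 0.15, 0.02 and 0.21, and histone genes 0.56, 0.10, 0.01 and 0.18. Members went both ways: in WT, 5 of 28 inflammatory genes were at least 2-fold higher and 8 lower, as were 5 and 4 of 13 histone genes. Topoisomerase genes had 0.70, 0.49, 0.09 and -0.26. Tdp1, which repairs topoisomerase adducts, was at least 2.0-fold higher in WT cells, and the topoisomerase II gene Top2a was at -1.06 ± 0.38. Top2b, the other topoisomerase II gene, was detected on the WT control but not on the WT amsacrine array. Heat shock genes had 0.18, -0.42, 0.39 and -0.07 (0.18, -0.32, 0.23 and -0.07 with undetected genes at their bounds). Oxidative stress (Nrf2) genes had 0.26, 0.46, -0.12 and 0.58 (0.05, 0.15, 0 and 0.46 with bounds). Of these, DNA repair and heat shock genes stood apart in Δ122p53, topoisomerases in WT, and oxidative stress genes in p53-null cells after amsacrine (8 of 19 at least 2-fold higher) and after irradiation, as they did between the null controls.

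Among cell type markers, plasma cell genes had medians of -0.88, -0.49, -0.04 and -0.38 in the same order, dendritic cell genes -0.54, -0.81, -0.08 and -0.24, megakaryocyte genes 0.19, 0.24, -0.13 and 0.07, and stromal genes 0.02, -0.01, -0.65 and 0.06. With undetected genes at their bounds these were -0.03, 0, 0 and -0.07 for dendritic cell genes, 0, 0.24, 0 and 0 for megakaryocyte genes and 0 for stromal genes in Δ122p53. Erythroid genes had -0.62 in WT, -0.23 in p53-null and 0.08 in Δ122p53 cells after amsacrine, and -0.12 after irradiation; with undetected genes at their bounds the WT median was 0. In Δ122p53 against WT, 5 of 7 megakaryocyte genes fell, with Ppbp at least 2.65-fold lower. In a model of the WT and p53-null arrays alone, chosen after seeing the data, 10 of 12 macrophage, 9 of 12 B cell and 9 of 16 mitotic genes fell after amsacrine, and 9 of 20 ribosome biogenesis genes rose. That model called 1265 genes, 443 without null control 2 and 3213 without null control 1. The sex-linked genes Eif2s3y (0.55 ± 0.66 in the WT response) and Kdm5d (0.34 ± 0.39) differed by less than their errors.

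Some aminoacyl-tRNA synthetase genes, which Atf4 induces, were higher after amsacrine, and a response of the whole family was a hypothesis. It stays open. The 10 members not noticed beforehand had medians of 0.26 in WT and 0.70 in p53-null cells after amsacrine and 0.34 after irradiation, with 9 of 10 higher each time, but lay at the 77.1th, 99.86th and 92.99th percentile of random lists. All 12 members, the noticed ones included, lay at the 96.13th, 100th and 99.62th percentile, with 11 higher each time.

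Lower MHC class II genes after amsacrine were noticed in Δ122p53 cells, where all 10 measured members were lower (median -1.70) and 7 at least 2-fold. Whether the other genotypes share the fall stays open. The 5 members not noticed beforehand had medians of -0.55 in WT (3rd percentile, 3 lower) and -0.14 in p53-null cells (17.7th percentile, 4 lower), too few genes to decide. All 10 had medians of -0.78 in WT (8 lower), -0.63 in p53-null cells (9 lower) and -0.88 after irradiation (9 lower), each below the 2.5th percentile. The median of the 5 was -0.90 in Δ122p53 cells, and the difference between genotypes was not tested.

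Amy2a5, pancreatic amylase, was among the genes lower on the Δ122p53 arrays, at 10.30 on the WT control and 9.58 on the WT amsacrine array against 5.33 and 5.13 on the Δ122p53 arrays. Pancreatic tissue carried along with the spleens may account for this: of 19 other exocrine pancreas genes with a probe, listed before the test, 10 were detected on the WT control and 0 on the Δ122p53 control, and after amsacrine 5 in WT, 2 in Δ122p53 and 1 in p53-null cells. On the WT control Cela1, 1 of the 19, was at 7.94, and the others of the 19 were at 6.67 or lower. The lowest detected signal on that array was 5.80. Cela2a at 7.83 and Ctrb1 at 7.59 had been noticed beforehand, like Amy2a5, and are not among the 19. The p53-null controls had 5 and 2 of the 19 detected and the irradiated array 2. Of these genes Ctrl was highest on the Δ122p53 amsacrine array (6.50), unlike Amy2a5. The labels name no sort that would remove such cells, and how many of these genes spleen cells also express was not tested.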
